A study of Mus musculus with 6 samples.

How the data were processed

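RNA from single cells was measured in mouse embryos of 3 genotypes at embryonic day 3.5 (E3.5) and E4.5, the early and late blastocyst. Per the labels, the genotypes were wild type (WT), knockout (KO) and knock-in (KI) for the microRNA miR-203, and mothers of the KI embryos were given doxycycline in their food from the day of the vaginal plug until collection. Each genotype and stage had 1 library, which gave 6 libraries. The number of embryos and litters behind each library is not given in the sources used here. Only the KI arm received the drug, so effects of the drug and of the transgene cannot be told apart in these comparisons. Per the labels' protocols, the zona pellucida of E3.5 embryos was dissolved in acid, cells were freed with a mixture of TrypLE and Accutase, and polyadenylated RNA was captured on a 10x Chromium with the 3' v3 chemistry.

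The deposited matrices hold counts of unique molecular identifiers (UMIs) per gene and barcode, not normalised by the authors. Per the submitters' processing notes, FastQC 0.11.9, STARsolo, STAR 2.7.10a and Scanpy 1.8.2 were used and the builds mm10 and GRCh38 were named; the deposited features are mouse genes only. Each deposited matrix covers 55487 genes and 6794880 barcodes of the chemistry's whitelist. The authors also deposited a list of barcodes taken as cells, for which no rule is given in the sources used here. No barcode outside a list had more UMIs than the lowest barcode in it, so a UMI threshold per library is compatible with each list. Further deposited matrices split the counts into spliced, unspliced and ambiguous UMIs.

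Cells were the listed barcodes with at least 500 genes and at most 25% of UMIs from mitochondrially encoded genes. This left out 2 barcodes of the E3.5 WT library, 76 of the E4.5 KO library and 1 of the E4.5 KI library. The 3 libraries of a stage were clustered together with Scanpy 1.11.5 (10000 counts per cell, log scale, 2000 variable genes without Xist and Y-linked genes, 30 principal components, 15 neighbours, Leiden resolution 0.5, leidenalg 0.10.2 and igraph 0.11.9). No deposited cell annotation was used. A cluster was called trophectoderm-like, inner cell mass or epiblast-like, or primitive endoderm-like from fixed markers when at least 3 of them were 2-fold or more above the other clusters (20 CPM, counts per megacount, added to both sides) and no other class led its top 10 genes. Doublets were called with Scrublet and kept (12, 12 and 13 cells of the E3.5 WT, KO and KI libraries, and 3, 7 and 28 of the E4.5 libraries), with an alternative that left them out. The free RNA of each library was taken from unlisted barcodes with over 10 and up to 1000 UMIs, and the median UMIs of unlisted barcodes with over 30 UMIs stood for an empty droplet.

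UMIs were summed over the cells of a library, or of a class within it, and scaled to CPM by the sum of its nuclear-encoded UMIs. Ratios are log2 of the CPM of the first-named library over the second, with exact 95% conditional Poisson intervals; a count of 0 was set to 3 counts. Shares of cells carry exact 95% Clopper-Pearson intervals. These intervals and limits cover counting error only. With 1 library per group, a comparison at 1 stage has no replicate and no residual degrees of freedom, so no p-value was computed. A model additive in genotype and stage would leave 2 residual degrees of freedom but takes differences between the stages as error, and was not used here. Counts of genes with a ratio of at least 2-fold, among genes with at least 100 UMIs in both libraries together, describe these libraries and do not count changed genes. A class was compared only with at least 20 cells in each library. Comparisons of single clusters (clusters 3 and 4 of the E3.5 KO library against WT classes, and trophectoderm-like cluster 2 of E4.5) were chosen after the clusters were seen.

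Gene lists, cell type markers, the rule for named genes and 12 alternatives were fixed before the data were examined. The named genes are, per comparison with WT, the 10 with the highest and the 10 with the lowest whole-library ratio among genes with at least 100 UMIs in both libraries together and at least 20 CPM in one of them. Xist, Y-linked, mitochondrially encoded and ribosomal protein genes and gene models without a symbol were left out, and the ratio had to have the same sign in each named class with at least 20 cells. Where a class had a count of 0, the sign was that of the ratio with 3 counts in its place, so it was not measured for Lefty2 in the trophectoderm-like KO cells or for Hspa1a and Hspa1b in the epiblast-like KO cells. Up to 10 genes each way that were at least 2-fold apart in the same direction at both stages were added, with the 2 to 4 members of a described list with the largest ratios; a few further list members named in the text were chosen after their values were seen. The lists cover markers of the 3 blastocyst classes, of reproductive tract epithelium, uterine stroma, cumulus or granulosa cells, erythroid cells, leukocytes and oocytes, 2-cell-stage genes, naive pluripotency, formative and primed pluripotency, polar and mural trophectoderm, histone acetyltransferases, histone deacetylases, DNA methylation machinery, histone methylation machinery, reported miR-203 targets, imprinted genes, the p53 response, the integrated stress response, immediate early and heat shock genes, glycolysis and hypoxia, cholesterol synthesis, nuclear genes of oxidative phosphorylation, mitochondrially encoded genes, S phase, G2 and M phase, FGF and ERK signalling, YAP targets, pyruvate and amino acid use, X inactivation, Y-linked genes and ribosomal proteins. For a list with at least 5 measured members, the median log2 ratio is given with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. Transcript length was not matched. The percentile is a description of these libraries.

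Sites for the miR-203-3p seed were the 8-mer CATTTCAA and the 7-mer CATTTCA in annotated 3' UTRs of at least 50 bases, from the GENCODE M21 annotation of GRCm38 (mm10). Genes were binned on UTR length (10 bins) and expression (5 bins). The adjusted difference is the median of site genes minus that of genes without a site after each bin's median of genes without a site was taken away, and it was set against that of 100 other 7-mers of like base content. No controls of the other site lengths were made. The percentile instead sets the plain median of site genes among random lists with the same number of genes per bin, drawn from genes without a site, or from all genes of a bin with too few of these. The alternatives were another cell filter, no cell filter, doublets left out, another Leiden resolution, each library clustered alone, median-of-ratios size factors, the mean over cells, classes weighted as in the WT library, at least 20 UMIs, a pseudocount of 10 CPM, and other seed matches. A further 4 were chosen after seeing the data: subtraction of free RNA, leaving out cluster 4 of the E3.5 KO library, leaving out trophectoderm-like cluster 0 of E4.5, and leaving out ribosomal protein genes, pseudogenes and genes with an annotated pseudogene named after them (called genes with copies). For genes with copies, ribosomal protein genes were recognised by how the symbol begins (Rps or Rpl and a digit, Rplp or Rpsa). This can take in some kinase genes with such symbols.

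The procedure was tested on simulated pairs of libraries with 200 genes changed by known folds. Both libraries of a pair were drawn with Poisson counting error from the WT profile, without variation between libraries, embryos or makeup of cells. The values check the computation and give no rate of false calls for the real comparisons. In the simulation of E3.5 KO against WT, 95.5% of the intervals over 8330 genes held the true ratio, all 50 genes raised 4-fold came out at least 2-fold higher, and 0 of 8136 unchanged genes came out 2-fold apart. In the simulation of E3.5 KI against WT, with 7967 genes, 95.6% of intervals held the truth and 4 of 7772 unchanged genes came out 2-fold apart. For E4.5 KO against WT, with 6446 genes, these values were 96.2% and 46 of 6252, and for E4.5 KI against WT, with 7552 genes, 94.9% and 0 of 7361. A shift of 0.2 given to all seed-site genes was found as 0.195, 0.196, 0.195 and 0.197 in the same order. Of 100 unchanged lists, 8, 3, 3 and 3 lay outside the central 95% of random lists. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, AnnData 0.12.19, scikit-learn 1.9.0 and Matplotlib 3.10.9 were used.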

Results

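Cells of mouse blastocysts that were wild type for the microRNA miR-203, lacked it or carried an inducible copy of it were profiled at E3.5 and E4.5, with 1 library per genotype and stage. At E3.5, 304 WT, 289 KO and 254 KI cells were kept, and at E4.5, 1314 WT, 465 KO and 950 KI cells. The libraries held 26574077, 20892162 and 26572324 UMIs (E3.5 WT, KO and KI) and 15868588, 4059758 and 13823436 UMIs (E4.5 WT, KO and KI) over all barcodes. The listed barcodes held 29.9%, 20.1% and 9.90% of these UMIs at E3.5 and 32.7%, 17.6% and 25.3% at E4.5. Median depth per cell was 23571.5, 13997 and 8976 UMIs at E3.5 and 2878, 1208 and 3348.5 UMIs at E4.5. The lowest UMI count in the barcode lists ranged from 270 in the E4.5 KO library to 4486 in the E3.5 WT library. The median UMIs of an empty droplet came to between 1.41% (E3.5 KO) and 10.5% (E4.5 WT) of the median cell.

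The targeted gene, Mir203 (ENSMUSG00000065574; chromosome 12, 112130880 to 112130955, mm10), had 0 UMIs in the cells of all 6 libraries. This allows up to 0.389, 0.723 and 1.18 CPM in the E3.5 WT, KO and KI libraries and up to 0.591, 4.61 and 0.875 CPM in the E4.5 libraries. A microRNA precursor is poorly captured by 3' sequencing of polyadenylated RNA, so the count of 0 checks neither the KO nor the KI label. The neighbouring gene Aspg (112106679 to 112127559) had 4, 15 and 2 UMIs in the E3.5 WT, KO and KI cells and 10, 0 and 2 in the E4.5 cells. Kif26a, on the other side (112146208 to 112181747), had 2, 0 and 3 UMIs at E3.5 and 28, 10 and 22 at E4.5.

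The first question was which cells made up each library. At E3.5 the WT library held 31.6% trophectoderm-like cells (96 cells, interval 26.4 to 37.1%), 65.5% inner cell mass or epiblast-like cells (199 cells, 59.8 to 70.8%) and 2.96% primitive endoderm-like cells (9 cells, 1.36 to 5.55%). The KI library held 25.2% (64 cells, 20.0 to 31.0%), 64.6% (164 cells, 58.3 to 70.4%) and 10.2% (26 cells, 6.80 to 14.6%) of the same classes. Cells of the KO library stood apart. Trophectoderm-like cells made up 19.7% of it (57 cells, 15.3 to 24.8%), or 10.2% with at least 2000 genes and at most 10% mitochondrial UMIs per cell. No cell was named inner cell mass-like or primitive endoderm-like (0 of 289), and the other 80.3% (232 cells, 75.2 to 84.7%) lay in unnamed clusters 3 and 4 that held KO cells alone. Clusters 0 to 2 held all WT and KI cells, and 55 of the 57 trophectoderm-like KO cells formed a cluster of their own, cluster 5, named from 3 markers and with a median of 6382 UMIs. These names depended on joint clustering: with each library clustered alone, 43.6% of KO cells (126 of 289) were named inner cell mass-like and 38.4% stayed unnamed, while 0% of WT cells were named inner cell mass-like. With 1 library per group, such clusters may reflect the library rather than a cell type. The division of WT and KI cells between inner cell mass and primitive endoderm also depended on the setting: with doublets left out, primitive endoderm-like cells made up 12.7% of the WT and 29.0% of the KI library.

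At E4.5, under the main cell filter, trophectoderm-like cells dominated the WT library and the primitive endoderm and epiblast classes the KO and KI libraries. The WT library held 82.3% trophectoderm-like cells (1082 cells, 80.2 to 84.4%), 5.02% epiblast-like cells (66 cells, 3.91 to 6.35%) and 12.6% primitive endoderm-like cells (166 cells, 10.9 to 14.6%). In the KO library these were 24.1% (112 cells, 20.3 to 28.2%), 34.2% (159 cells, 29.9 to 38.7%) and 41.7% (194 cells, 37.2 to 46.4%). In the KI library they were 26.63% (253 cells, 23.8 to 29.6%), 26.63% (253 cells) and 46.7% (444 cells, 43.5 to 50.0%). At Leiden resolution 1.0 the KO trophectoderm-like share was 8.17%, as 74 KO cells formed an unnamed cluster of KO cells alone. Trophectoderm-like cells came from cluster 0 (1020 WT, 5 KO and 27 KI cells, median 2432 UMIs) and cluster 2 (62 WT, 107 KO and 226 KI cells). Cluster 0 was nearly all from the WT library and may stand for that library rather than a kind of cell. The lowest listed UMI count differed too, at 1434 in the WT, 270 in the KO and 834 in the KI library. Among cells above each library's median UMI count the trophectoderm-like share was 66.5% (62.8 to 70.1%), 27.5% (21.8 to 33.7%) and 29.1% (25 to 33.4%). Under a stricter cell filter (at least 2000 genes and at most 10% mitochondrial UMIs per cell), the WT share was 42.9% and the KI share 31.6%.

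**Figure D1:**
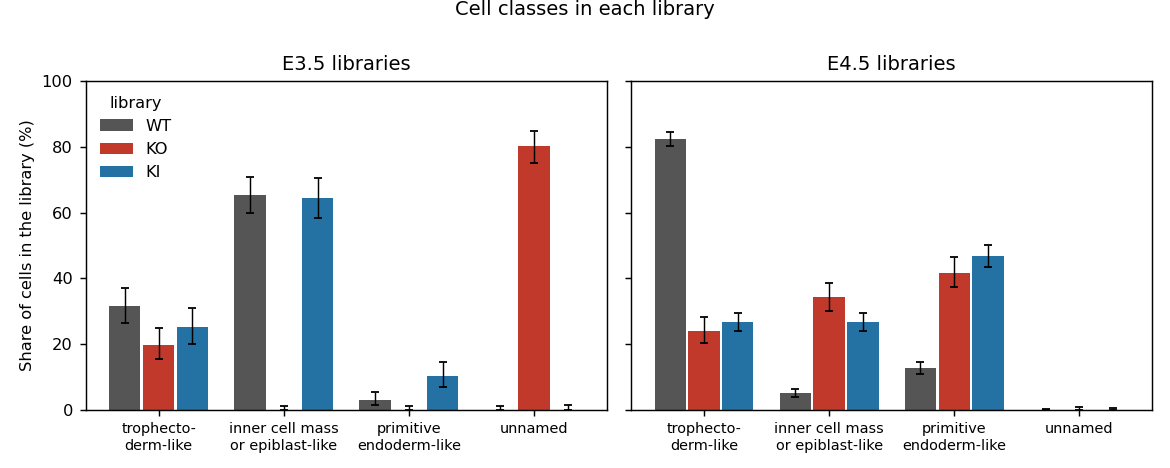
Share of cells per class (percent, y axis) in each of the 6 libraries, with bars for exact 95% binomial intervals that cover counting error only. Unnamed cells made up 80.3% of the E3.5 KO library (38.4% with each library clustered alone), and trophectoderm-like cells 82.3% of the E4.5 WT library (42.9% with at least 2000 genes and at most 10% mitochondrial UMIs per cell) against 24.1% (KO; 8.17% at resolution 1.0) and 26.63% (KI).

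The course from E3.5 to E4.5 within each genotype gave the axis along which the title places fate transitions. In WT cells, formative pluripotency genes were higher in the E4.5 epiblast-like than in the E3.5 inner cell mass-like class (8 of 8 measured, all at least 2-fold, median log2 ratio 2.88, percentile 100 among random lists). Otx2, a transcription factor of the exit from naive pluripotency, stood at 243 CPM against 22.5 (3.43, interval 3.05 to 3.82), and the de novo DNA methyltransferase gene Dnmt3b at 560 against 69.1 CPM (3.02, 2.79 to 3.25). Naive pluripotency genes had a median of -0.61 (percentile 0.03, 4 of 16 higher), with Dppa3, a maternal and germline factor, at -4.44 (-4.76 to -4.13) and Nanog at -2.60. Glycolysis genes had a median of 1.5 (14 of 15 higher), led by Ldha at 5.71 (5.4 to 6.03). Cholesterol synthesis genes had one of 1.49 (9 of 10 higher), with Cyp51 at 3.06. KI cells showed the same directions in this class: formative genes at 2.25 (7 of 7 higher), naive genes at -0.65 (5 of 15 higher), glycolysis at 1.41 (14 of 14) and cholesterol synthesis at 1.74 (8 of 9). In these cells Otx2 stood at 2.25 (1.75 to 2.78), Dnmt3b at 2.35 (2.05 to 2.67) and Dppa3 at -3.62 (-3.82 to -3.43). The KI primitive endoderm-like class, with 26 cells at E3.5, had a median of 1.72 for primitive endoderm markers (20 of 22 higher; Dab2, an endocytic adaptor, at 6.48), -1.33 for naive genes and 2.46 for cholesterol synthesis (16 of 16). Among trophectoderm-like KI cells, trophectoderm markers had a median of 1.15 (14 of 19 higher), with the keratin gene Krt19 at 6.16, the placental gene Plac1 at 4.99 and the early trophectoderm factor Cdx2 at -2.36.

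Whole libraries of all genotypes had higher primitive endoderm markers at E4.5, with medians of 2.41 in WT (20 of 22 higher), 3.21 in KO (16 of 18) and 2.15 in KI (20 of 22). Naive genes were lower, with medians of -1.37 (1 of 16 higher), -0.96 (3 of 15) and -0.95 (1 of 16). Glycolysis genes had medians of 1.72, 1.40 and 1.63, and cholesterol synthesis genes of 1.25, 1.3 and 1.73. Immediate early and heat shock genes had a median of 2.72 in WT (15 of 16 higher) and 2.01 in KI, and of 0.17 in KO (percentile 56). Of the genes with at least 100 UMIs, 871 were at least 2-fold higher and 1151 lower at E4.5 in WT (of 8710), 718 and 937 in KO (of 5913) and 560 and 586 in KI (of 6756). With median-of-ratios size factors the KO counts became 408 and 1276, so that 24.2% in place of 43.4% of these genes were higher, and the median of all genes moved from 0.07 to -0.23.

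The KO comparison at E3.5 asked how cells without miR-203 differed from WT cells in the early blastocyst. Trophectoderm markers were lower in the KO library (13 of 15 measured, median -1.46, percentile 0), with the keratin gene Krt18 at -1.87 (-1.97 to -1.77), the transcription factor gene Gata2 at -2.49 (-3.66 to -1.5) and Dppa1 at -2.14 (-2.38 to -1.91). Mural trophectoderm genes had a median of -1.14 (percentile 0), although Hand1, a trophoblast factor, stood at 2.27 (1.88 to 2.68). Of the primitive endoderm markers (median -0.36), Foxq1 stood at -3.08 (-4.43 to -1.99), Sox17 at -1.55 (-2.14 to -1.01) and Serpinh1, a collagen chaperone gene, at 1.60 (1.29 to 1.93). Of the inner cell mass markers (median -0.19) Spp1 stood at -1.45 and Nanog at -0.79. Ribosomal protein genes were higher in the KO library (71 of 84 measured, 43 at least 2-fold, median 1.08, percentile 100). Mt1 (metallothionein; chromosome 8, 94179082 to 94180327) stood at 553 CPM in KO and 4040 in WT cells (-2.87, -2.93 to -2.81), and the mitochondrially encoded genes had a median of -0.48. The 10 highest named genes, Olfr1423, Retn, Usp50, Acmsd, Vmn1r15, Spopfm2, Slfn5, Cyp4x1, Cyp2e1 and Ccdc125, had ratios from 4.38 to 4.95. Retn encodes the hormone resistin and Cyp2e1 a cytochrome P450. Usp50 (ENSMUSG00000027364.14; chromosome 2, 126709096 to 126783470) stood at 4.87 (4.20 to 5.62), and Spopfm2 at 4.66, or -0.28 with cluster 4 left out. Besides Mt1, the 10 lowest were St6galnac4, a sialyltransferase gene, at -6.03 (-8.32 to -4.47, 3 KO UMIs), Adh1 at -4.13, Ipp at -3.34, Mir6236 at -3.25, Ncoa7, Prxl2b, Wipf1, the imprinted noncoding RNA gene Kcnq1ot1 at -2.51 and Cyct at -2.50. The only 2-cell-stage gene with 100 UMIs, Sp110, stood at 4.32 (3.95 to 4.70). Sp110 was first among the top genes of cluster 4, which held KO cells alone. It also reached 100 UMIs in cluster 4 against WT inner cell mass-like cells. No 2-cell-stage gene did so for cluster 3 or for the trophectoderm-like KO cells. The ratio of Sp110 in the whole library therefore need not hold across KO cells.

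Within E3.5 classes, the trophectoderm-like KO cells (57 cells, 55 of them in cluster 5) against those of WT (cluster 0) had a median of -0.54 for trophectoderm markers (percentile 0.57), -0.93 for mural genes and -1.02 for p53 response genes, with the cell cycle inhibitor gene Cdkn1a at -1.45 (-2.80 to -0.36). In the whole KO library, however, Cdkn1a was higher, at 1.08 (0.85 to 1.31), and it stood at 1.94 (1.66 to 2.23) in cluster 4 against WT inner cell mass-like cells. Ribosomal protein genes had a median of 1.28 (percentile 100) in the trophectoderm-like KO cells. KO cluster 3 against WT inner cell mass-like cells had ratios near the all-gene median for inner cell mass markers (-0.15, percentile 52) and primitive endoderm markers (-0.18, percentile 49). It had higher trophectoderm markers (0.34, percentile 99.4) and higher FGF and ERK genes (0.60), among them Spry2 at 1.33 and Fgfr2 at 1.17. KO cluster 4 against the same WT cells had higher trophectoderm markers (1.90, percentile 100), with Gata3 at 4.84 (4.40 to 5.30) and Cdx2 at 2.84 (2.41 to 3.29). Against WT trophectoderm-like cells, however, the trophectoderm markers of cluster 4 were lower (13 of 14, 11 at least 2-fold, median -3.14, percentile 0). Against the inner cell mass-like cells it had lower inner cell mass markers (-1.48, percentile 0), with Spp1 at -5.92 (-6.53 to -5.36). In the whole library, 639 genes were at least 2-fold higher and 825 lower of 8437. With median-of-ratios size factors these were 787 and 556, so that 58.6% in place of 43.6% were higher, and the median of all genes moved from -0.20 to -0.03. With cluster 4 left out, 424 genes were higher.

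The KI comparison at E3.5 asked what added miR-203, with doxycycline, went along with. Primitive endoderm markers were higher in the KI library (14 of 17 measured, 5 at least 2-fold, median 0.59, percentile 100), in a library with 10.2% primitive endoderm-like cells against 2.96% in WT. Inner cell mass or epiblast markers were higher as well (13 of 18, median 0.21, percentile 100). Serpinh1 (ENSMUSG00000070436.12; chromosome 7, 99345376 to 99353239) led at 1.66 (1.3 to 2.01), with the laminin gene Lama1 (chromosome 17, 67697259 to 67822647) at 1.52 (1.07 to 1.97), the transcription factor genes Foxq1 at 1.45 (1.04 to 1.86) and Sox17 at 1.35 (1.03 to 1.67), and the endocytic receptor gene Cubn at 1.54. Inside the inner cell mass-like class (cluster 1 in both libraries), primitive endoderm markers had a median of 0.28 (percentile 100), with Serpinh1 at 1.28 (0.78 to 1.78) and Sox17 at 0.97 (0.59 to 1.35). The mix of cells differed too: at resolution 1.0 a cluster led by Fgf4, Spic and Klf2 held 120 WT and 76 KI cells, and one with Sox17, Sparc and Pdgfra among its top genes 79 WT and 89 KI cells. Trophectoderm markers of the class had one of 0.33 (percentile 100), with Krt18 at 1.36 (1.07 to 1.65). An empty droplet came to 3.69% of the median cell in the KI library against 1.95% in WT. Free RNA was subtracted for whole libraries only, so its part in ratios inside this class was not tested. Inside the trophectoderm-like class (cluster 0 in both), trophectoderm markers had a median of 0.35 and mural genes one of 0.42 (both percentile 100), with Tspan8 at 1.18 (1.05 to 1.31) and Gata2 at 0.89 (0.33 to 1.42). The p53 target Cdkn1a (chromosome 17, 29090976 to 29100727) was lower, at -1.17 (-1.66 to -0.70) in the library and -1.07 (-1.68 to -0.51) in the inner cell mass-like class. The other highest named genes were the stress regulator gene Nupr1 at 1.48, Eps8, Aqp8, Rcn1, Creb3l2 and Adh1 at 1.10. The lowest were Rab26os at -1.79, Arhgap42 at -1.65, Naalad2, the alkaline phosphatase gene Alppl2 at -1.16 (-1.33 to -1.0), Rdh10, Zfp820, the noncoding RNA gene Neat1 at -1.05, Stard4 and Pemt. In the library as a whole 20 genes were at least 2-fold higher and 36 lower of 7988, against 16 and 57 of 5188 in the trophectoderm-like and 6 and 20 of 6552 in the inner cell mass-like class. The whole-library counts became 4 and 6 with a pseudocount of 10 CPM, and 226 and 349 with at least 20 UMIs.

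Among metabolic, stress and cell cycle lists in the E3.5 KI library, nuclear genes of oxidative phosphorylation had a median of 0.15 (31 of 32 higher, percentile 100), glycolysis genes of 0.27 (12 of 15, percentile 100) and integrated stress response genes of 0.20 (15 of 18, percentile 99.9), with Trib3 at 1.00 (0.48 to 1.51) and Asns at 0.94 (0.73 to 1.16). YAP targets had a median of -0.39 (percentile 0.2), with Ccn2 at -0.93 (-1.53 to -0.37). S phase genes had a median of 0.10 (percentile 99.8), G2 and M phase genes of -0.15 (percentile 0), cholesterol synthesis genes of 0.15 (percentile 92) and immediate early and heat shock genes of -0.14 (percentile 9.6). In the KO library these lists had medians of -0.10 (oxidative phosphorylation), -0.32 (glycolysis; 0.23 without genes with copies), -0.23 (integrated stress response), -0.59 (YAP targets), -0.33 (S phase), -0.25 (G2 and M phase), -0.28 (cholesterol synthesis) and 0.11 (immediate early and heat shock; -0.14 with free RNA subtracted), at percentiles between 7.8 and 89.5. Hspa8, a constitutive heat shock gene, stood at 2.36 (2.28 to 2.43) in the KO library, and the DNA polymerase gene Pola1 at 2.39 (2.27 to 2.51).

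For the late blastocyst, timely transitions were addressed first in the class that passes from naive to formative pluripotency, the epiblast-like cluster 3, with 66 WT, 159 KO and 253 KI cells. The cells differed in quality: with each library clustered alone, epiblast-like cells had medians of 6714.5 (WT), 1084 (KO) and 3436 UMIs (KI), and of 2.42%, 4.20% and 2.40% mitochondrially encoded UMIs. Formative genes were lower in both genotypes: 6 of 6 measured in KO cells (median -0.82, percentile 0.05) and 9 of 9 in KI cells (median -0.54, percentile 0). Dnmt3a stood at -1.92 (-2.96 to -1.02) in KO and -0.97 (-1.37 to -0.57) in KI cells, Otx2 at -1.02 (-1.71 to -0.39) and -0.81 (-1.16 to -0.45), and Dnmt3b at -0.61 (-1.0 to -0.24) and -0.54 (-0.76 to -0.32). The neural and epiblast factor gene Pou3f1 stood at -1.66 (-2.19 to -1.14) in KI cells and the Wnt effector gene Lef1 at -1.33 (-2.01 to -0.71) in KO cells. Naive genes were higher, with medians of 0.48 (KO, percentile 99.4) and 0.38 (KI, 11 of 12, percentile 99.97). Dppa3 stood at 1.22 (0.75 to 1.69) in KO and 0.68 (0.32 to 1.06) in KI cells, Nanog at 1.07 (0.38 to 1.80) in KI cells and Klf2 at 0.82 (0.43 to 1.20) in KO cells, whereas the naive marker Zfp42 stood at -1.02 (-1.39 to -0.67) in KO cells. Spp1, an inner cell mass marker, stood at 1.25 and 1.16. Glycolysis genes were lower (KO -0.55, percentile 0.03; KI -0.18, percentile 0.68), with Pkm at -1.46 and Ldha at -1.03 in KO cells, and nuclear oxidative phosphorylation genes higher (0.24 and 0.26). Ribosomal protein genes had a median of 0.86 in the KO cells (percentile 100). Both comparisons used the same 66 WT cells, so part of their likeness may come from that shared control.

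In the E4.5 primitive endoderm-like class, cluster 1 with 166 WT, 194 KO and 444 KI cells, KO and WT cells parted at resolution 1.0: 178 KO cells lay with 4 WT cells in a cluster with a median of 1487 UMIs, and 162 WT cells lay with 16 KO cells in another. With each library clustered alone, primitive endoderm-like cells had medians of 6218 (WT), 1216.5 (KO) and 3205 UMIs (KI). Their median shares of mitochondrially encoded UMIs were 1.75%, 3.74% and 1.85%. Over the whole class, Dppa3 was again higher, at 1.77 (1.21 to 2.32) in KO and 1.15 (0.73 to 1.59) in KI cells. DNA methylation genes had a median of 0.53 in KO cells (percentile 99.9), with Dnmt3b at 0.75 (0.54 to 0.96) and Dnmt3a at 0.64 (0.26 to 1.01), and of -0.17 in KI cells (percentile 6.4). Imprinted genes were lower in KI cells (7 of 7, median -0.61, percentile 0), with Peg3 at -0.93 (-1.22 to -0.64) and Kcnq1ot1 at -0.69 (-0.93 to -0.46), and Peg3 stood at -0.95 (-1.53 to -0.41) in KO cells. Histone acetyltransferase genes had a median of -0.50 in KI cells (percentile 0.04), with the coactivator genes Crebbp at -0.80 (-1.15 to -0.46) and Ep300 at -0.66 (-1.11 to -0.21). Cholesterol synthesis genes had one of 0.33 (14 of 17 higher, percentile 100), with Mvd at 0.78 and Idi1 at 0.65. Primitive endoderm markers had one of -0.20 (6 of 22 higher, percentile 0), with Cubn at -0.63 (-0.73 to -0.54). In KO cells Cubn stood at -0.96 (-1.15 to -0.76) and Cited1, a transcriptional coregulator gene, at -2.37 (-3.14 to -1.69), in a marker list with a median of -0.12 (percentile 18.5). In trophectoderm-like cluster 2 (62 WT, 107 KO and 226 KI cells), trophectoderm markers had medians of 0.18 in KO (percentile 94) and 0.25 in KI cells (percentile 99.98), with the fatty acid binding protein gene Fabp3 at 0.41 and 0.48 and Dppa1 at 0.76 and 1.00. The X-linked homeobox gene Rhox5 stood at -0.82 (-1.53 to -0.17) and -1.26 (-1.65 to -0.87), and the imprinted noncoding RNA gene H19 at -1.09 (-1.51 to -0.66) in KI cells.

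Over whole E4.5 libraries the marker lists went with the shares of cells and with differences inside the trophectoderm-like class. Trophectoderm markers had medians of -1.13 (KO, 20 of 20 lower) and -0.71 (KI, 19 of 20 lower), inner cell mass or epiblast markers of 0.60 and 0.58, and primitive endoderm markers of 0.42 and 0.30. With classes weighted as in the WT library these medians became 0.09 and 0.24, -0.77 and -0.75, and -0.77 and -0.77, so each reversed. Inside the trophectoderm-like class (KO and KI cells mostly of cluster 2, WT cells mostly of cluster 0), primitive endoderm markers had medians of -2.09 (KO) and -1.60 (KI), with 0 of 17 higher in each, and epiblast markers of -1.24 and -1.61. Mural genes, at -0.64 and -0.26, became 0.03 and 0.17 in the same way. Polar genes stood at -0.16 and -0.14, against -0.15 and -0.03 in the E3.5 KO and KI libraries. In the KO library, the named gene with the highest ratio was Pigp (ENSMUSG00000022940.17; chromosome 16, 94358763 to 94371842), which acts in the synthesis of glycosylphosphatidylinositol anchors, at 797 against 82.3 CPM (3.27, 3.09 to 3.46). It was followed by Wdr89 at 2.24, the Nodal antagonist gene Lefty2 at 2.18 (1.76 to 2.60), the Wnt antagonist gene Sfrp1 at 2.17, Cyp4f14, the glutamate transporter gene Slc1a3 at 2.04, the complex I gene Ndufb4, Arhgef40, Brd1 at 1.91 and H2ac8. Lefty2 stood at 1.5 (0.83 to 2.16) in the epiblast-like and 1.09 (0.47 to 1.68) in the primitive endoderm-like KO cells. The lowest were Ipp (chromosome 4, 116507549 to 116538243) at -4.52 (-7.57 to -2.65, 2 UMIs), H2bc4 at -3.81 (-9.12 to -1.3, 1 UMI), Hspa1b at -3.35 (-5.64 to -1.79, 3 UMIs), Baiap2l1, Hspa1a, Gadd45g at -2.60, Aif1l, Ccdc85c, the thymosin gene Tmsb10 (chromosome 6, 72957347 to 72958748) at -2.31 (-2.48 to -2.14) and Ulk4. Tmsb10 stood at -1.38 in the epiblast-like, -1.33 in the primitive endoderm-like and -1.51 in the cluster 2 KO cells.

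In the KI library the highest ratio was that of Brd1 (chromosome 15, 88687034 to 88734233), a subunit of histone acetyltransferase complexes, at 2.03 (1.79 to 2.27). It stood at 2.08 (1.41 to 2.81) in the epiblast-like, 1.68 (1.25 to 2.14) in the primitive endoderm-like and 1.34 (0.81 to 1.90) in the cluster 2 KI cells. It stood at 2.06, 1.31 and 1.46 in the same KO cells. The casein kinase gene Csnk2a2 followed at 1.44 (1.26 to 1.62) and stood at 1.44 (1.15 to 1.73) in the KO library, then the DNA repair gene Ercc8 at 1.31, the mRNA export gene Alyref2, Pawr, Tcea3, Dnajc21, Hnrnpa0, Ttc5 and Spty2d1. The lowest were Plekho2 at -1.97, Rpgrip1 at -1.90, the transcription factor gene Ets2 (chromosome 16, 95702075 to 95721051) at -1.79, Fasl, Efs, H19 at -1.22, S100g, the ERK phosphatase gene Dusp6 at -1.19 (0.30 with cluster 0 left out), Jdp2 at -1.14 (0.06 under the stricter cell filter) and the lipid droplet gene Plin2 at -1.13. In the KO library 275 genes were at least 2-fold higher and 292 lower of 6504, and in the KI library 39 and 85 of 7611. With median-of-ratios size factors these were 137 and 447 (23.5% in place of 48.5% higher) and 27 and 120 (18.4% in place of 31.5% higher). The median of all genes moved from 0.07 to -0.13 and from 0.07 to -0.02. With the mean over cells they were 669 and 375 (64.1% higher) and 438 and 219 (66.7% higher). With classes weighted as in WT they were 307 and 628 (32.8% higher) in KO and 130 and 202 (39.2% higher) in KI, and without cluster 0 they were 105 and 127 in KO and 19 and 23 in KI. Under the stricter cell filter they were 8 and 11 in KI.

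**Figure D2:**
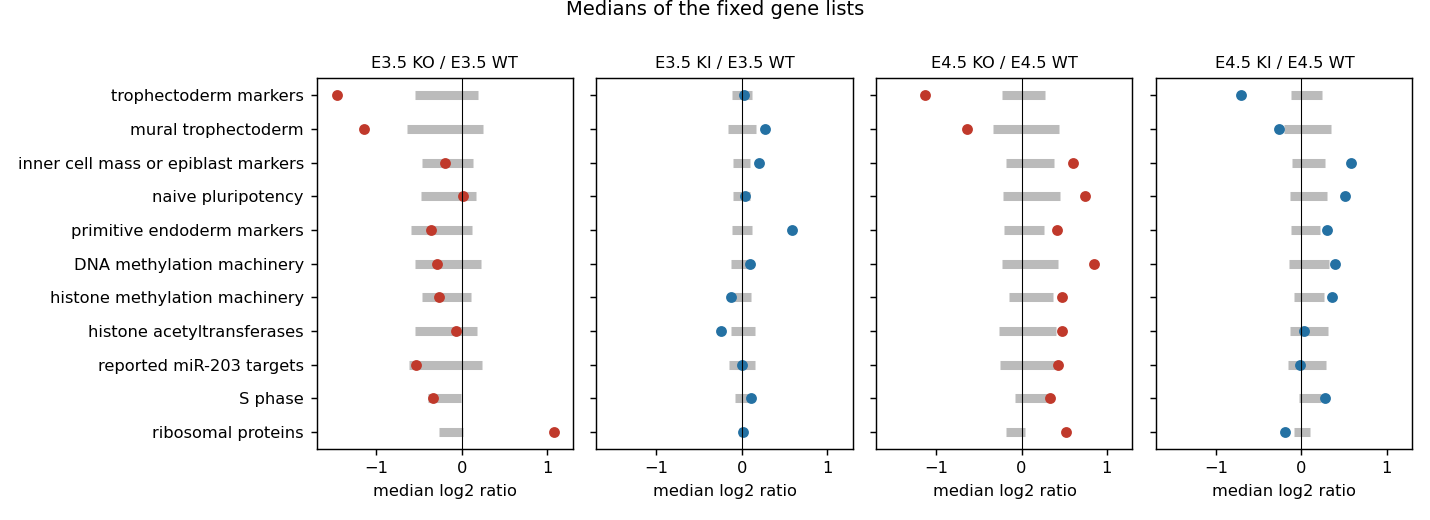
Median log2 ratio to WT of each gene list in the KO and KI libraries of both stages, with grey bars for the central 95% of 10000 random lists matched on expression. Trophectoderm markers lay at -1.46 in the E3.5 KO library, and at -1.13 (KO) and -0.71 (KI) at E4.5, where they reversed with classes weighted as in WT.

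The title names epigenetic modulation, and the lists of chromatin regulators bear on it. The random lists were not matched on transcript length. Across genes, KI ratios had Spearman rho of -0.171 (E3.5) and 0.235 (E4.5) with transcript length. How far length enters the medians and percentiles of these lists was not tested. At E3.5, histone acetyltransferase genes had a median of -0.24 in the KI library (11 of 13 lower, percentile 0.11), with Kat7 at -0.55 (-0.83 to -0.28) and Ep300 at -0.36 (-0.62 to -0.10). Histone methylation genes had one of -0.12 (18 of 23 lower, percentile 0.81), with Kmt2a at -0.39 (-0.66 to -0.12). Inside the trophectoderm-like KI cells these lists had medians of -0.33 (percentile 1.15) and -0.31 (percentile 0.12). Histone deacetylase genes had medians of 0.15 in the KO and 0.14 in the KI library, and DNA methylation genes of -0.29 and 0.10. Reported miR-203 targets had medians of -0.53 (percentile 5.5) and 0.00, with Socs3 at 3.13 (2.59 to 3.72), Lasp1 at 1.20 (0.98 to 1.43) and Zfp281 at -1.07 (-1.52 to -0.63) in the KO library. In that library Dnmt3b stood at -1.05 (-1.28 to -0.83), Dnmt3a at 0.48 (0.24 to 0.72), Kmt2a at -1.44 (-1.74 to -1.15) and the deacetylase gene Hdac1 at 1.15 (1.03 to 1.26), with acetyltransferase and histone methylation medians of -0.06 and -0.27. At E4.5, DNA methylation genes had a median of 0.85 in the KO library (12 of 12 higher, percentile 100), with the methylcytosine dioxygenase gene Tet1 at 1.43 (1.18 to 1.67) and the imprint guardian Zfp57 at 1.64 (1.07 to 2.18). The makeup of the libraries differed, with 34.2% epiblast-like cells in KO against 5.02% in WT. Inside classes, Dnmt3a and Dnmt3b were lower in epiblast-like and higher in primitive endoderm-like KO cells than in those of WT. In the KI library the DNA methylation median was 0.39 (percentile 99.4; -0.31 with classes weighted as in WT and -0.19 without cluster 0). Histone methylation genes had medians of 0.47 in KO (21 of 21 higher, percentile 99.8) and 0.36 in KI (percentile 99.8; -0.22 without cluster 0), acetyltransferase genes of 0.47 and 0.02, deacetylase genes of 0.45 and 0.31 (KI -0.05 without cluster 0), and reported targets of 0.43 (percentile 97.6) and -0.02. Inside the epiblast-like KI cells, reported targets had a median of -0.43 (percentile 0.12), with Dnmt3a and Dnmt3b among them, and histone methylation genes one of -0.22 (percentile 1.0), with the Polycomb genes Suz12 at -0.52 (-0.76 to -0.28) and Ezh2 at -0.49 (-0.77 to -0.21).

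Other lists over whole E4.5 libraries followed the makeup of the libraries in part. Cholesterol synthesis genes had medians of 0.25 in KO (-0.13 without cluster 0) and 0.56 in KI (18 of 19 higher, percentile 100), with Msmo1 at 0.98 (0.83 to 1.14). Naive genes had medians of 0.74 (12 of 13) and 0.51 (14 of 15; -0.15 with classes weighted as in WT). Naive genes stood at 0.02 and 0.04 and formative genes at -0.48 and 0.24 in the E3.5 KO and KI libraries, and formative genes at -0.01 and 0.09 at E4.5. Immediate early and heat shock genes had medians of -0.48 in KO (14 of 16 lower, percentile 0.45) and -0.07 in KI. S phase genes had medians of 0.33 (-0.05 with classes weighted as in WT) and 0.28 (-0.07 without cluster 0), and G2 and M phase genes of 0.26 and 0.22 (-0.21 and -0.24 without cluster 0). Nuclear oxidative phosphorylation genes had medians of -0.14 and -0.20 (0.37 and 0.26 without cluster 0) and mitochondrially encoded genes of 1.10 in KO and -0.23 in KI (0.10 without cluster 0), against 0.20 in the E3.5 KI library. Glycolysis genes had medians of -0.21 and 0.02, integrated stress response genes of -0.11 and -0.08, p53 response genes of -0.25 and 0.03, and YAP targets of -0.13 and 0.10. FGF and ERK genes had medians of 0.30 and 0.14, and pyruvate and amino acid genes of 0.03 and 0.06. Imprinted genes had medians of 0.11 and -0.19, against -0.29 and -0.09 at E3.5, where p53 response genes had 0.12 and -0.11, FGF and ERK genes -0.36 and 0.15, and pyruvate and amino acid genes -0.32 and 0.06.

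Markers of cells from outside the embryo were rare. No gene of the uterine stroma, erythroid or oocyte lists reached 100 UMIs in any pair of libraries compared with WT. Of the reproductive tract list, Wfdc2 stood at -2.34, 0.14, -0.44 and -0.37 (E3.5 KO, E3.5 KI, E4.5 KO, E4.5 KI) and Msx1 at 0.46 and 0.24 at E4.5. Of the cumulus list, Has2 stood at -0.31 and -0.36 at E4.5, and of the leukocyte list S100a8 at -0.26 and -1.26 and S100a9 at -0.04 and -1.16. The sex-linked RNAs differed too: Xist, which silences an X chromosome in females, stood at 0.38, -0.56, 1.40 and 1.51 in the same order, and the Y-linked genes Ddx3y at -0.97, -0.19, 0.06 and -0.49 and Eif2s3y at -1.60, 0.42, -0.62 and -0.52. Unspliced UMIs made up 17.7%, 20.8% and 17.1% of spliced and unspliced UMIs in the E3.5 WT, KO and KI cells and 12%, 22.1% and 16.1% in the E4.5 cells, so both KO libraries had the largest share of their stage. Mitochondrially encoded UMIs made up 2.87%, 1.34% and 3.37% of UMIs at E3.5 and 2.30%, 4.0% and 2.01% at E4.5.

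A comparison of the stages asked which genes went the same way in both. In KO libraries, 75 genes were at least 2-fold higher at both stages (10.6 by independence, from 248 and 264 of 6200) and 43 lower (20.0, from 594 and 209). Pigp was higher by 3.54 (3.40 to 3.68) and 3.27, Wdr89 by 3.06 and 2.24, Arhgef40 by 4.35 and 1.92, Ndufb4 by 1.91 and 1.98, and the ribosomal fusion gene Fau by 2.17 and 1.67, followed by Xaf1, the Polycomb gene Pcgf2, Serf2, the replication gene Ticrr and Snhg6. Of these 75, 51 (68.0%, 56.2 to 78.3%) were ribosomal protein genes, pseudogenes or genes with a named pseudogene, against 6.11% of all genes. The lowest were Ipp (-3.34 and -4.52), H2bc4, Baiap2l1, Ndrg1, the keratin genes Krt8 (-1.46 and -1.40) and Krt18 (-1.87 and -1.26), Gng2, Lgals3, Csta1 and Lrp2. However, Krt8, Krt18, Gng2, Lgals3 and Csta1 had E4.5 ratios of 0.24, 0.40, 0.02, 0.28 and 0.40 without cluster 0. In KI libraries 0 genes were 2-fold apart at both stages (0.0775 higher and 0.0778 lower by independence). Ribosomal protein genes had medians of 1.08 and 0.52 in the KO libraries (50 of 83 higher at E4.5, percentile 100), and of 0.01 and -0.19 in the KI libraries (14 of 84 higher at E4.5; 0.10 without cluster 0).

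**Figure D3:**
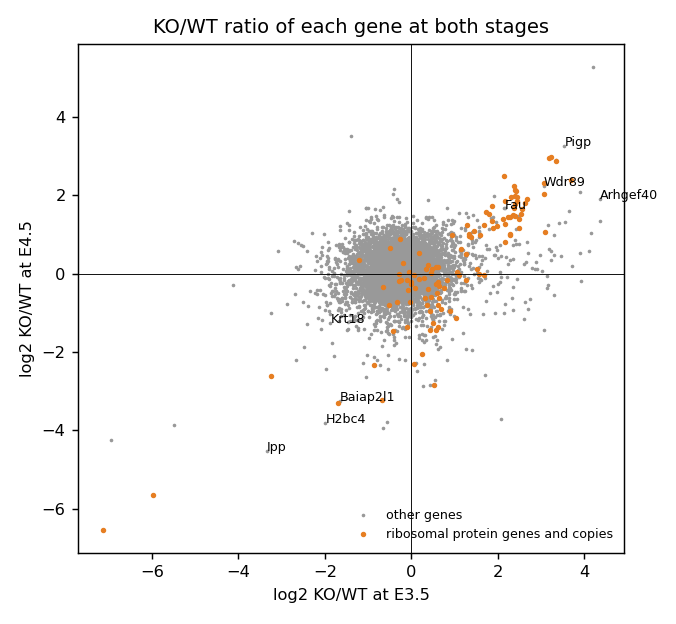
Log2 ratio of KO to WT at E3.5 (x axis) and E4.5 (y axis) for 6200 genes, with ribosomal protein genes and copies named after them in orange. They were recognised by how the symbol begins, which can take in some kinase genes with such symbols. Other pseudogenes and other genes with a named pseudogene are among the grey points. Pearson r across genes was 0.217, and Pigp lay at 3.54 and 3.27.

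Across genes, which are not independent replicates, KO ratios at E3.5 and E4.5 had Pearson r = 0.217 and Spearman rho = 0.083 (6200 genes). This r was 0.105 without genes with copies, 0.0865 with classes weighted as in WT and 0.361 without cluster 0 of E4.5. KI ratios had r = -0.077 and rho = -0.093 (7021 genes), or r = 0.129 without cluster 0. Along the stage axis of the third genotype, r was -0.009 for E3.5 KO, -0.154 for E4.5 KO, 0.311 for E3.5 KI and 0.099 for E4.5 KI, or -0.020 for the last without cluster 0 (rho 0.014, -0.116, 0.253 and 0.118). Genes higher at E4.5 in the KO libraries thus tended to be higher in E3.5 KI than in E3.5 WT cells. KO and KI ratios at a stage share the WT library. At E3.5, over 7900 genes, they had r = -0.067 (covariance -0.0150) where simulated unchanged groups with counting error only gave 0.299 (0.0089). At E4.5, over 6502 genes, they had r = 0.553 (covariance 0.130) where these gave 0.216 (0.0095). At E3.5, 2 genes were higher and 6 lower in both KO and KI (0.722 and 3.75 by independence), and at E4.5, 11 and 51 (0.756 and 3.23). With 1 WT library the control could not be divided, so part of the E4.5 excess may come from it.

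Genes with miR-203 seed sites in the 3' UTR addressed direct repression, which would leave them lower in KI and higher in KO cells than in WT. In the E3.5 KI library, 1309 site genes of 7578 had a median of -0.0302 where random matched lists had -0.0184 (percentile 1.28). The difference adjusted per bin of UTR length and expression was -0.030, and all 100 control 7-mers gave a higher value. This difference depended on the setting: it was -0.014 with 8-mer sites alone, -0.017 with 6-mer sites included, -0.018 with doublets left out and -0.0062 with the mean over cells. In its trophectoderm-like cells the difference was -0.056 (98 of 100 controls higher), and in its inner cell mass-like cells -0.008 (75 of 100). In the E4.5 KI library it was 0.019 (59 of 100 controls higher; 1253 site genes) and -0.023 without cluster 0. Its classes went both ways, with 0.076 in trophectoderm-like (12 of 100 controls higher), -0.022 in epiblast-like (72 of 100) and -0.006 in primitive endoderm-like cells (63 of 100). In the epiblast-like cells the plain median of site genes, -0.0530, lay above that of random matched lists, -0.0578 (percentile 63.3), so the sign there depended on the statistic. The trophectoderm-like values set KI and KO cells mostly of cluster 2 against WT cells mostly of cluster 0. The E3.5 KO library gave -0.087 (79 of 100 controls higher; 1350 site genes), with -0.094 in trophectoderm-like cells (88 of 100), opposite in sign to lost repression. With 6-mer sites included it was -0.202, although the plain medians of site genes and random matched lists (-0.325 and -0.249) lay close to those with 7-mer sites (-0.333 and -0.254). The E4.5 KO library gave 0.055 (21 of 100; 1055 site genes), or -0.026 without cluster 0. Its classes gave 0.032 in trophectoderm-like (54 of 100), -0.085 in epiblast-like (99 of 100) and -0.033 in primitive endoderm-like cells (84 of 100).

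**Figure D4:**
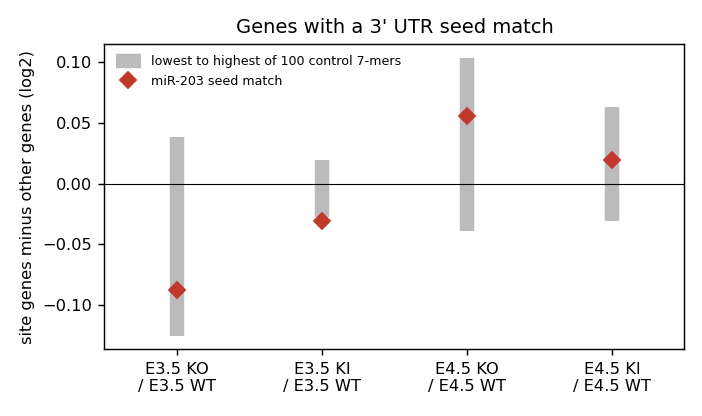
Difference in median log2 ratio to WT between genes with a miR-203 seed site and genes without one, adjusted per bin of UTR length and expression, with grey bars from the lowest to the highest of 100 control 7-mers. In the E3.5 KI library the difference of -0.030 lay below all 100 controls, but it was -0.014 with 8-mer sites alone, -0.017 with 6-mer sites included and -0.0062 with the mean over cells. The difference was -0.087 in the E3.5 KO and 0.055 in the E4.5 KO library.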

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

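The test of a batch, the test of genes with copies, the tests of shares with at least 2000 genes per cell (alone or with at most 10% mitochondrial UMIs), and the reading of the transcript length test by its opposite signs at the stages were chosen after the results were seen. The first pattern is that E3.5 KO cells formed clusters of their own: 99.3% of them lay in clusters of at least 90% KO cells. Depth is argued against, since 100% did so with every cell thinned to 5000 UMIs (47 KO, 2 WT and 34 KI cells were shallower and left out). With cluster 4 left out, 98.4% of the other KO cells still lay apart, so cluster 4 alone does not make up the pattern. This was largely set beforehand, as clusters 3 and 5 already held 132 and 55 KO cells and no WT or KI cells. It cannot decide on cells of an earlier stage in clusters 3 and 5. Without ribosomal protein genes, pseudogenes and genes with a named pseudogene, 98.3% lay apart, so reads of these genes alone do not account for it. Genes whose pseudogenes are not named after them were kept, so reads shared with those stay open. A batch of library preparation cannot be told apart from the genotype with 1 library per group; across genes the KO ratios of the stages had r = 0.217. The missing microRNA itself stays among the open explanations, as untested.

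The second pattern is the 118 genes at least 2-fold apart between KO and WT in the same direction at both stages. A chromosome segment of another strain beside Mir203 is argued against, since 0% of them lay within 20 Mb of it (upper limit 3.08%; 0.984% of all genes). Transcript length is argued against as a cause of like ratios at both stages, since its correlation with the KO ratio was -0.105 at E3.5 and 0.276 at E4.5 across genes (-0.171 and 0.235 for KI), although the E3.5 value lies only just outside the bound of 0.1 set before. Reads shared between copies are a candidate explanation for the higher genes, of which 68.0% were ribosomal protein genes, pseudogenes or genes with a named pseudogene (6.11% of all genes). Of the 43 lower genes 10 were such genes, a smaller share than among the higher genes but also above that of all genes. A difference in how the KO reads were processed, a variant of the strain and the genotype all stay open for the other genes.

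The third pattern is the larger share of trophectoderm-like cells in the E4.5 WT library. The lowest listed UMI count was higher in WT (1434) than in KI (834) and KO (270). The median empty droplet also held more UMIs in WT (302) than in KI (129) and KO (39). The lowest counts therefore cannot show which threshold was more permissive. Shallow cells among the listed WT barcodes stay open. Among cells above each library's median UMI count the WT share was 2.29 times the KI share and 2.42 times the KO share. With at least 2000 genes per cell and the main classes kept, however, it was 1.40 times the KI share (42.9% against 30.7%). With at most 10% mitochondrial UMIs as well and cells clustered again it was 1.36 times (42.9% against 31.6%). The bound set before on the first test was too weak to settle this, since that test kept 657 WT cells and each of the later ones 375. Droplets of free RNA counted as cells stay open: WT cells of cluster 0 had a median of 2453.5 UMIs against 6405 in other WT cells, and 6.99% of 7687 genes were 2-fold or more apart between them and the free RNA of the library (r = 0.946), while primitive endoderm markers were lower in KO (-2.09) and KI (-1.60) than in WT trophectoderm-like cells. A loss of cells of one class during dissociation, the number of embryos and the genotype also stay open, as untested.

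The remaining results had opposite directions at the stages, and the difference between stages was not tested for any of them. The KI ratio had a median of -0.15 at E3.5 and 0.22 at E4.5 for G2 and M phase genes. For histone methylation genes these were -0.12 and 0.36. For mural trophectoderm genes they were 0.27 and -0.26. For nuclear oxidative phosphorylation genes they were 0.15 and -0.20. Without cluster 0 the 4 E4.5 values were -0.24, -0.22, 0.49 and 0.26, each with the sign of E3.5. Across genes, KI ratios also had opposite correlations with transcript length at the stages (Spearman rho -0.171 and 0.235). The part of length in these lists was not tested. In KO libraries the heat shock gene Hspa1a stood at 3.31 at E3.5, from 16 KO UMIs against 0 WT UMIs taken as 3, and at -2.71 at E4.5 (2 KO UMIs; -5.77 to -0.82). Hspa1b stood at 2.34 and -3.35. The seed-site difference in KO libraries was -0.087 at E3.5 and 0.055 at E4.5 (-0.0258 without cluster 0).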

How the results depend on the processing

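Of the 16 alternatives, 4 were chosen after seeing the data: free RNA subtracted, E3.5 KO cluster 4 left out, E4.5 cluster 0 left out, and genes with copies left out. Over 253 results and 2377 values, 2029 stayed within a margin set for their kind of value (1.5 times for a count). Another 307 were counted as moved and 41 as reversed, and these 41 do not include every change of sign. List medians moved in 85 and were counted as reversed in 29 of 1007 values, and single-gene ratios in 154 and 11 of 1081. Some list medians given above, such as that of G2 and M phase genes in E4.5 KO without cluster 0, changed sign without being so counted. Counts of higher and of lower genes moved in 15 of 47 each, shares of cells in 24 of 92, and correlations in 5 of 56. Seed-site differences moved in 9 and were counted as reversed in 1 of 47. Without cluster 0, some values counted as moved also changed sign: the E4.5 KI seed-site difference (0.0193 to -0.0232), the KI correlation between stages (-0.077 to 0.129) and that of E4.5 KI with the stage axis (0.099 to -0.020). Stage was not used as a block in a model over the 6 libraries. With at least 2000 genes and at most 10% mitochondrial UMIs per cell the E4.5 KO library kept 9 cells, all primitive endoderm-like (66.4 to 100%). This is under the minimum of 20, so no E4.5 KO ratio, list or seed-site value is given under that filter, a rule applied after this was seen. The cause was not tested for any of these.

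Without E3.5 KO cluster 4, higher KO genes numbered 424 (639) and Spopfm2 stood at -0.28 (4.66). With at least 20 UMIs, higher and lower genes numbered 1505 and 1650 (E3.5 KO), 226 and 349 (E3.5 KI), 875 and 820 (E4.5 KO) and 246 and 360 (E4.5 KI), with more genes counted. With a pseudocount of 10 CPM there were 297 lower genes in E3.5 KO, 4 and 6 in E3.5 KI, 145 and 158 in E4.5 KO, and 10 and 24 in E4.5 KI. Median-of-ratios size factors gave 137 and 447 in E4.5 KO. The mean of cells gave 669 higher genes in E4.5 KO, 438 and 219 in E4.5 KI, and seed-site differences of -0.0062 (E3.5 KI) and 0.0433 (E4.5 KI).

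Without E4.5 cluster 0, higher and lower genes numbered 105 and 127 in KO and 19 and 23 in KI. List medians in KO and KI were 0.25 and 0.51 for trophectoderm markers, -0.37 and -0.44 for primitive endoderm markers and 0.28 and 0.49 for mural genes. In KI they were -0.19 for DNA methylation, -0.22 for histone methylation, 0.26 for oxidative phosphorylation, -0.0743 for S phase, -0.24 for G2 and M phase and 0.10 for ribosomal protein genes, and Dusp6 stood at 0.30. In KO, Krt8 stood at 0.24, Krt18 at 0.40, Gng2 at 0.0175, Lgals3 at 0.28 and Csta1 at 0.40. The correlation between stages was 0.361 in KO and 0.129 in KI, that of E4.5 KI with the stage axis -0.020, and the E4.5 seed-site differences -0.0258 (KO) and -0.0232 (KI).

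With classes weighted as in WT, E4.5 KO had 628 lower genes and E4.5 KI 130 higher and 202 lower. E4.5 medians in KO and KI were 0.0902 and 0.24 for trophectoderm, -0.77 and -0.75 for inner cell mass or epiblast and -0.77 and -0.77 for primitive endoderm markers, and 0.0299 and 0.17 for mural genes. In KI they were -0.15 for naive and -0.31 for DNA methylation genes, and in KO -0.0505 for S phase genes. There Krt18 stood at 0.0351, Lgals3 at 0.0116 and Csta1 at 0.0099. The KO correlation between stages was 0.0865. Without genes with copies it was 0.105.

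With at least 2000 genes and at most 10% mitochondrial UMIs per cell, E4.5 KI had 8 higher and 11 lower genes. E3.5 shares were 56.8% inner cell mass and 11.9% primitive endoderm in WT, 10.2% trophectoderm and 89.8% unnamed in KO, and 47.5% inner cell mass and 29.6% primitive endoderm in KI. E4.5 shares were 42.9% trophectoderm, 17.3% epiblast and 39.7% primitive endoderm in WT, and 31.6% trophectoderm and 41.8% primitive endoderm in KI. E4.5 KI medians were 0.0882 for trophectoderm markers, -0.28 for primitive endoderm markers, 0.0247 for mural, -0.0111 for DNA methylation, -0.0403 for S phase and -0.0184 for G2 and M phase genes, Jdp2 stood at 0.0631, and the seed-site difference was 0.000797. At Leiden resolution 1.0, inner cell mass shares at E3.5 were 39.5% (WT) and 29.9% (KI), and the E4.5 KO trophectoderm share 8.17%. With each library clustered alone, E3.5 WT had 0% inner cell mass and 0% primitive endoderm, KO 43.6% inner cell mass and 38.4% unnamed, and KI 24.8% inner cell mass and 30.3% primitive endoderm. With doublets left out, E3.5 inner cell mass and primitive endoderm shares were 55.5% and 12.7% (WT) and 45.2% and 29.0% (KI), and the E3.5 KI seed-site difference -0.0179. With 6-mer sites included, the seed-site difference was -0.202 (E3.5 KO, although site genes had a median of -0.325 and random matched lists of -0.249, close to -0.333 and -0.254 with 7-mer sites), -0.0168 (E3.5 KI) and 0.0382 (E4.5 KI), and with 8-mer sites alone -0.0142 (E3.5 KI).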

Other observations

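The comparisons of E4.5 cluster 2 and of E3.5 KO cluster 4 were chosen after the clusters were seen, and genes named here after their values were seen. In the KI cells of trophectoderm-like cluster 2 at E4.5 (226 of the 253 KI cells of this class), imprinted genes had a median of -0.54 (percentile 0.34), mural trophectoderm genes of 0.37 (percentile 99.96) and S phase genes of -0.22 (percentile 0.54). Plet1, a trophoblast progenitor surface gene, stood at 0.77 (0.40 to 1.15) in KI and 1.90 (1.45 to 2.34) in KO cells of this cluster. At resolution 1.0, however, 74 KO cells formed an unnamed cluster without WT or KI cells, with Gsto1 and Plet1 as its top genes. The replication gene Atad2 stood at -0.91 (-1.40 to -0.41) in KI cells. The glycolytic genes Pkm and Ldha stood at -1.73 (-2.49 to -1.05) and -1.08 (-1.57 to -0.62) in KO cells.

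G2 and M phase genes had medians of -0.25 in KO (percentile 0.16) and -0.19 in KI (percentile 0) primitive endoderm-like cells at E4.5, and of -0.17 (percentile 0) in E3.5 KI inner cell mass-like cells, where the spindle gene Nusap1 stood at -0.81 (-1.23 to -0.42). In E4.5 epiblast-like KI cells the centromere genes Hjurp and Cenpe stood at -0.87 (-1.45 to -0.29) and -0.81 (-1.26 to -0.37). Imprinted genes had a median of -0.36 in these cells (percentile 1.0), with Rian at -0.79 (-1.37 to -0.20) and Meg3 at -0.46 (-0.81 to -0.10). In E3.5 KO cluster 4 against WT inner cell mass-like cells, glycolysis genes had a median of -1.37 (percentile 0) and imprinted genes one of -1.54 (percentile 0.04). Outside cells, Mir203 had 1 UMI in the free RNA of the E4.5 KI library and 0 in that of the other 5.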
